A study of Homo sapiens with 6 samples.

How the data were processed

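RNA from HCT116 cells, a human colorectal carcinoma line, was measured on 6 Agilent 1-colour gene expression arrays, 1 per sample, labelled with Cy3. Per the labels, 3 samples received a control small interfering RNA (si-NC) and 3 a small interfering RNA against the circular RNA circSTK3 (si-circSTK3). The labels number the samples of each group 1 to 3 and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. A free-text label on every sample speaks of tissue, whereas title and source name the cell line, and the samples were treated as the cell line.

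The scanner files hold intensity values per spot, which per the file headers were made with Agilent Feature Extraction 11.0.1.1: the processed signal is background-subtracted within the array and has no scaling between arrays. The version is also given in the submitters' processing notes. The authors deposited a second table with 1 column of log2 values per array. Set against the scanner values, each of its columns followed the processed signal in rank order (Spearman correlation of at least 0.999), all columns had a median of 6.39, and the values lay a median of 0.000255 from a quantile normalization of the log2 processed signal. Its scale and direction were therefore taken as known, and it was used only as an alternative. The normalization program behind it is not given in the sources used here. No saturated spot was seen on any array.

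Each array held 43118 spots for 34127 gene probes, of which 999 probes had 10 spots each, and 1377 control spots. Spots marked as outliers by the scanner software, 216 to 459 per array, were left out, and spots of a probe were averaged. The files used here give accessions but no gene names for the probes. Accessions without their versions were matched to RefSeq names of the assembly GRCh38.p14, which named 25771 probes with 19740 gene symbols and left 8356 probes unnamed. The file headers name an older genome build, so no coordinates are given.

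The main values were log2 of the processed signal minus the 75th percentile of the array, so a level of 0 is the 75th percentile. A probe entered if it was well above background on all 3 arrays of at least 1 group, which kept 25826 probes. A gene was represented by its probe with the highest mean over the 6 arrays, and unnamed probes were kept one by one, which gave 21529 features, 16042 of them named genes. Differences are si-circSTK3 minus si-NC on the log2 scale, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 2.57 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is limma's moderated standard error and SD is the spread between the arrays of a group. The median SE over all features was 0.18. On simulated arrays with the spread of the 6 real ones and 200 changed genes among 21529, the fit recovered 49.3% of 2-fold and 92.9% of 4-fold changes and made 8.90 false calls on average over 10 simulations. With only the spread within a slide it recovered 86.6% and 98.5% and made 12.1 false calls, so the spread between arrays limits what can be found. The number of arrays was not varied. The simulated arrays held no shift shared by the arrays of a slide, so these shares do not cover such a shift.

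Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, beside camera with an estimated correlation and fry. The 33 lists covered cell division (E2F and G1/S genes, G2/M and mitosis genes, replication-dependent histones), stress and signalling (p53 targets, type I interferon response, NF-kB and inflammatory cytokines, immediate early and AP-1 genes, ATF4 integrated stress response, unfolded protein response, heat shock proteins, NRF2 and ferroptosis, apoptosis regulators, autophagy and lysosome, metallothioneins), metabolism (hypoxia and glycolysis, oxidative phosphorylation, cholesterol biosynthesis, fatty acid synthesis and lipid storage), colorectal and Hippo biology (Wnt targets, Hippo/YAP targets, Hippo kinases and adaptors, TGF-beta and BMP targets, intestinal differentiation), adhesion and invasion (epithelial junction and keratin genes, mesenchymal genes, matrix proteases, integrins and focal adhesion), RNA and protein synthesis (ribosomal proteins, ribosome biogenesis and MYC targets, small RNA machinery) and markers of other cell types (immune, fibroblast and endothelial, erythroid and blood). Each had 8 to 25 members measured.

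Genes named in the text were set by rule: those past the threshold, or with none past it the 10 smallest p among genes whose groups did not overlap and whose symbols were not clone or locus names. In addition, the member with the smallest p in each list was named where none passed, as was STK3, the host gene of the circular RNA. Of the genes this rule gave, 2 are not reported here. The groups, the test, this rule, the lists and the first set of alternatives were fixed before the data were examined.

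Per the file headers the arrays came from 2 slides. Slide 1 held the 3 si-NC arrays and si-circSTK3 replicate 1, and slide 2 held si-circSTK3 replicates 2 and 3. With the slide as a block, the treatment difference equals si-circSTK3 replicate 1 against the 3 si-NC arrays, with a spread pooled over both slides and the lone array assumed to vary like the others. Replicates 2 and 3 of si-circSTK3 correlated at 0.996 with each other, the highest of all pairs of arrays. They were counted as separate samples because the labels number them so, and 2 hybridizations of 1 RNA were not excluded.

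The alternatives set beforehand were quantile normalization, normexp background correction with an offset of 50 under both scalings, no filter, a filter on all 6 arrays, the mean over the probes of a gene, trended and robust variances, the replicate number or the slide as a block, the deposited log2 table, and each array left out. Normexp was run on the median spot signal, because a column of mean spot signals was not used here. Alternatives added after the data were seen were slide 1 alone, brighter genes only (mean above the 75th percentile level) with and without the replicate block, and quantile normalization without si-circSTK3 replicate 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.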

Results

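Gene expression was measured in HCT116 colorectal carcinoma cells that had received a small interfering RNA against circSTK3, a circular RNA that shares its gene with the linear STK3 transcript, or a control small interfering RNA, with 3 arrays per group. Circular RNAs are closed loops made by back-splicing, and the study asked which genes change with circSTK3 in colorectal cancer. The 75th percentile of the signal was 464 to 486 on the si-NC arrays and 322, 429 and 445 on si-circSTK3 replicates 1, 2 and 3. The share of probes well above background was 96.1%, 79.1% and 73.9% on si-NC replicates 1, 2 and 3 and 73.7%, 94.6% and 95.3% on the si-circSTK3 arrays. The first principal component, with 59.0% of the variance, set si-circSTK3 replicates 2 and 3, which shared a second slide, apart from the other 4 arrays. The second, with 24.5%, set replicate 1 of both groups apart from the rest.

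The signal for STK3, a kinase of the Hippo pathway, differed between the groups by less than the spread between arrays. Its probe A_33_P3260669 gave a log2 level relative to the 75th percentile of 0.88 ± 0.26 (SD, n = 3) in si-NC and 0.80 ± 0.17 (SD, n = 3) in si-circSTK3. The difference was -0.07 (SE 0.18, limma adjusted p = 0.880), and with the slide as a block it was 0.11 (adjusted p = 0.850). The probe was matched to the linear transcript by accession. Whether its sequence is also part of circSTK3 was not checked, and no value can be given for circSTK3. The depth of silencing in each sample was therefore not measured here.

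The genes with the smallest p between si-circSTK3 and si-NC were CES1P1, a carboxylesterase pseudogene, and EPB42, a protein of the red cell membrane skeleton, followed by MROH2B, the protocadherin PCDH12, the microtubule-associated kinase MAST4, the exocyst subunit EXOC6B, the axonemal dynein protein DNAI7, the granulocyte receptor CEACAM3 and the complement receptor C5AR2. All 9 lay higher on each si-circSTK3 array than on any si-NC array, and none passed the threshold. The rule took only genes whose groups did not overlap, so this separation was set by the choice of genes. CES1P1 (probe A_23_P374892) was at -5.88 ± 0.34 (SD, n = 3) in si-NC and -3.87 ± 0.12 (SD, n = 3) in si-circSTK3, a 4.03-fold difference (log2 2.01, SE 0.19, limma adjusted p = 0.260). EPB42 (A_23_P140675) was at -3.78 ± 0.18 and -2.59 ± 0.02, a difference of 1.19 (SE 0.13, adjusted p = 0.281). MAST4 (A_23_P110571) was at -3.14 ± 0.02 and -1.60 ± 0.35, a difference of 1.54 (SE 0.19), and C5AR2 (A_33_P3223002) was at -5.95 ± 0.71 and -3.41 ± 0.07, a difference of 2.54 (SE 0.34). The differences of MROH2B, PCDH12, EXOC6B, DNAI7 and CEACAM3 were 1.74, 2.07, 1.08, 1.44 and 2.36, each with an adjusted p of 0.281. On slide 1 alone, where only si-circSTK3 replicate 1 stood for the silenced cells, the difference was 2.14 for CES1P1, 1.16 for EPB42, 1.93 for MAST4 and 2.45 for C5AR2. That array was also used to choose these genes, so these values are not a separate check. All 9 genes were dim: 9 lay below the median signal and 8 among the 5382 dimmest features, and CES1P1, MROH2B, PCDH12, CEACAM3 and C5AR2 were well above background on 1 of the 3 si-NC arrays. With normexp background correction and 75th percentile scaling all 9 differences fell by more than 1.5 times, to 0.04 for CES1P1, 0.18 for EPB42, 0.20 for PCDH12, 0.60 for MAST4 and 0.17 for C5AR2, and CEACAM3 changed sign, to -0.07. With normexp and quantile normalization the 9 lay between 0.18 and 0.63. With quantile normalization alone 7 fell by more than 1.5 times, and CES1P1 was at 1.01, EPB42 at 0.69 and C5AR2 at 1.63.

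**Figure D1:**
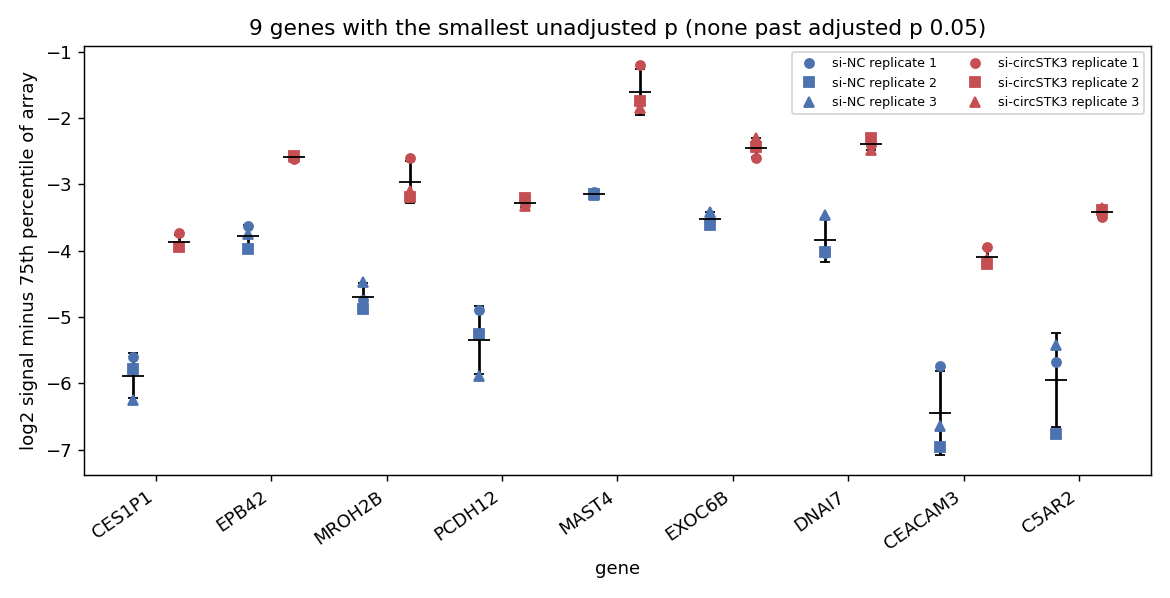
Log2 signal relative to the 75th percentile of the array for 9 genes with the smallest p. Each point is an array, blue for si-NC and red for si-circSTK3, with the shape giving the replicate; horizontal marks and bars are the mean and SD of 3 arrays. In each gene the 3 si-circSTK3 arrays lie above the 3 si-NC arrays, as for CES1P1 (-3.87 against -5.88). The genes were chosen for groups that do not overlap. All levels are below the 75th percentile at 0.

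Over 21529 features, limma called 0 past an adjusted p of 0.05, 0 higher and 0 lower, and so 0 with at least a 2-fold change; the smallest adjusted p was 0.260. At an unadjusted p under 0.05 there were 3538 features, 3077 higher and 461 lower in si-circSTK3, and with quantile normalization 1709 higher and 1689 lower. With normexp background correction and 75th percentile scaling there were only 482, 194 higher and 288 lower. With normexp and quantile normalization there were 2783, 1549 higher and 1234 lower. Both the number and its balance thus moved with the processing. The groups did not overlap in 3865 features (18.0%), against the 10% that chance gives for 3 exchangeable arrays against 3. The arrays were not exchangeable, since 2 of the 3 si-circSTK3 arrays were alone on slide 2, and a shift of that slide also pushes the groups apart. The count rested on single arrays. Without si-circSTK3 replicate 1, 5294 features passed, 4100 higher and 1194 lower, and with quantile normalization as well 5661 passed, 2427 higher and 3234 lower. Without si-NC replicate 1, 8 passed, all higher, among them CATSPERB (log2 2.68), CATSPERT (2.67), CCDC169 (2.37), CEACAM3 (2.72) and FABP3 (2.08). With the slide as a block 2 passed, LTA, a lymphotoxin cytokine, at -4.10 (SE 0.16, adjusted p = 0.0104) and the unnamed probe A_33_P3240687 at 5.89 (SE 0.27, adjusted p = 0.0114). Both were singled out after their values were seen, and both rested on 1 array: LTA was at -6.43 on si-circSTK3 replicate 1 and between -2.68 and -2.18 on the other 5, and A_33_P3240687 was at 1.07 against -5.22 to -3.84. On si-circSTK3 replicate 1 LTA lay below the median of the adenoviral E1A control probes (-3.98). Its level there was near the floor, so the size of its difference is not exact.

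Among cell division genes, E2F and G1/S genes (25 measured) had a median difference of -0.07 and G2/M genes (25) of -0.04, and no member passed. The members with the smallest p were the replication factor RFC3 at -0.32 (SE 0.15) and the mitotic kinesin KIF23 at -0.25 (SE 0.12). The 12 replication-dependent histones had a median of 0.02, with H2BC21 at 0.71 (SE 0.19). Ribosome biogenesis and MYC targets (22) had a median of -0.03, with NOP16 at -0.33 (SE 0.14), ribosomal proteins (22) of 0.03, with RPL32 at 0.28 (SE 0.11), and the small RNA machinery (13) of 0.04, with the exportin XPO5 at 0.24 (SE 0.16), for which 1 of 2 other probes had the opposite sign.

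Hypoxia and glycolysis genes (23), which cover the response to low oxygen and glucose use, had a median difference of 0.19, with the glucose transporter SLC2A3 at 1.04 (SE 0.31). SLC2A3 was well above background on 1 si-NC array, and its difference was -0.17 with normexp background correction. Oxidative phosphorylation genes (20) had a median of 0.07 with COX6C at 0.39 (SE 0.17), cholesterol biosynthesis genes (20) of -0.04 with the synthase HMGCS1 at -0.34 (SE 0.15), and fatty acid and lipid storage genes (15) of 0.06 with DGAT2 at 0.74 (SE 0.26). Immediate early and AP-1 genes (23) had a median of 0.22 with FOSL2 at 0.74 (SE 0.23), and NF-kB targets and cytokines (15) of 0.26 with the chemokine CXCL2 at 0.62 (SE 0.18). The type I interferon list (18) had a median of 0.08 with IRF7 at 0.56 (SE 0.18), p53 targets (24) of 0.08 with EDA2R at 1.05 (SE 0.22), and NRF2 and ferroptosis genes (21) of 0.02. Heat shock proteins (14) had a median of -0.10 with the chaperone HSPA8 at -0.35 (SE 0.24). The unfolded protein response (17) had HSP90B1 at -0.29 (SE 0.21) and the ATF4 list (20), with a median of 0.10, had NUPR1 at 0.97 (SE 0.46); with the slide as a block these 2 genes turned to 0.17 and -0.14. Apoptosis regulators (25) had a median of 0.03 with BMF at 0.79 (SE 0.17), metallothioneins (11) of 0.17 with MT1E at 0.42 (SE 0.15), and autophagy and lysosome genes (21) of 0.03 with LAMP2 at -0.52 (SE 0.13), whose 2 other probes had the opposite sign.

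Hippo/YAP targets (21), which the pathway of STK3 restrains, had a median difference of -0.004 with FOXF2 at 1.11 (SE 0.36), and Hippo kinases and adaptors (17) of 0.02 with VGLL4 at 0.52 (SE 0.16). Wnt targets (17) had a median of 0.13 with the intestinal stem cell factor ASCL2 at 0.92 (SE 0.25). TGF-beta and BMP targets (13) had a median of 0.19; PMEPA1 was at 0.77 (SE 0.16) and SKIL, named after its values were seen, at 0.64 (SE 0.17), and adjusted over the list alone these 2 passed, both higher, whereas no other list had such a member. With the slide as a block SKIL was at 0.42, and PMEPA1 was at 0.28 with normexp background correction. Mesenchymal genes (17) had a median of 0.19 with ZEB2 at 1.12 (SE 0.38), matrix proteases (20) of 0.17 with MMP14 at 1.08 (SE 0.32), integrins and focal adhesion genes (20) of 0.08 with ITGA3 at 0.51 (SE 0.20), epithelial junction and keratin genes (23) of 0.04 with JUP at 0.34 (SE 0.11), and intestinal differentiation genes (17) of 0.09 with TFF1 at 0.58 (SE 0.18). Markers of immune cells (15), fibroblasts and endothelium (8) and blood (9) had medians of 0.11, 0.32 and 0.13, which turned to -0.23, -0.34 and -0.19 with quantile normalization, and their members with the smallest p were CD68 at 0.59 (SE 0.21), VWF at 0.71 (SE 0.26) and the globin HBB at 1.09 (SE 0.29).

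None of the 33 lists passed. The smallest adjusted p with camera was 0.0718, shared by E2F and G1/S genes and heat shock proteins, with an estimated correlation the smallest adjusted p was 0.999, and with fry 0.573. The median was above 0 in 27 lists and below 0 in 6, and above 0 in 22 with quantile normalization. Its sign held in 19 lists under quantile normalization and both normexp settings and turned in 14 under at least 1 of them, among them the interferon, mesenchymal, intestinal, ribosome biogenesis, E2F and G2/M lists. In 15 lists the median, the mean and camera's direction were not all of 1 sign; camera compares a list with all other genes, whose median difference was 0.09. Of the 32 list members named by their smallest p, the slide as a block reduced 15 by more than 1.5 times. They were ZEB2 (0.22), MMP14 (0.36), FOXF2 (0.31), DGAT2 (0.16), VWF (0.14), XPO5 (0.02), HMGCS1 (-0.15), CXCL2 (0.27), H2BC21 (0.40), EDA2R (0.62), ASCL2 (0.52), VGLL4 (0.32), MT1E (0.26), TFF1 (0.32) and HBB (0.50). It raised the size of 4 as much, COX6C (0.61), RFC3 (-0.51), NOP16 (-0.52) and HSPA8 (-0.87), and turned NUPR1 and HSP90B1. Between the slides within si-circSTK3, replicates 2 and 3 against the single array of replicate 1, 7 of the 32 passed, among them ZEB2 (adjusted p = 0.0219) and MMP14 (0.0370). Quantile normalization reduced 11 of the 32 as much, and normexp with 75th percentile scaling 18, with 2 more that turned. Among the 18 were EDA2R (0.14), FOXF2 (0.16), ASCL2 (0.12), ZEB2 (0.20), IRF7 (0.06) and VWF (0.01). These were dim genes, with si-NC means from -4.01 for ZEB2 to -2.65 for IRF7. The adjusted p of the list members named above ran from 0.281 to 0.526.

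**Figure D2:**
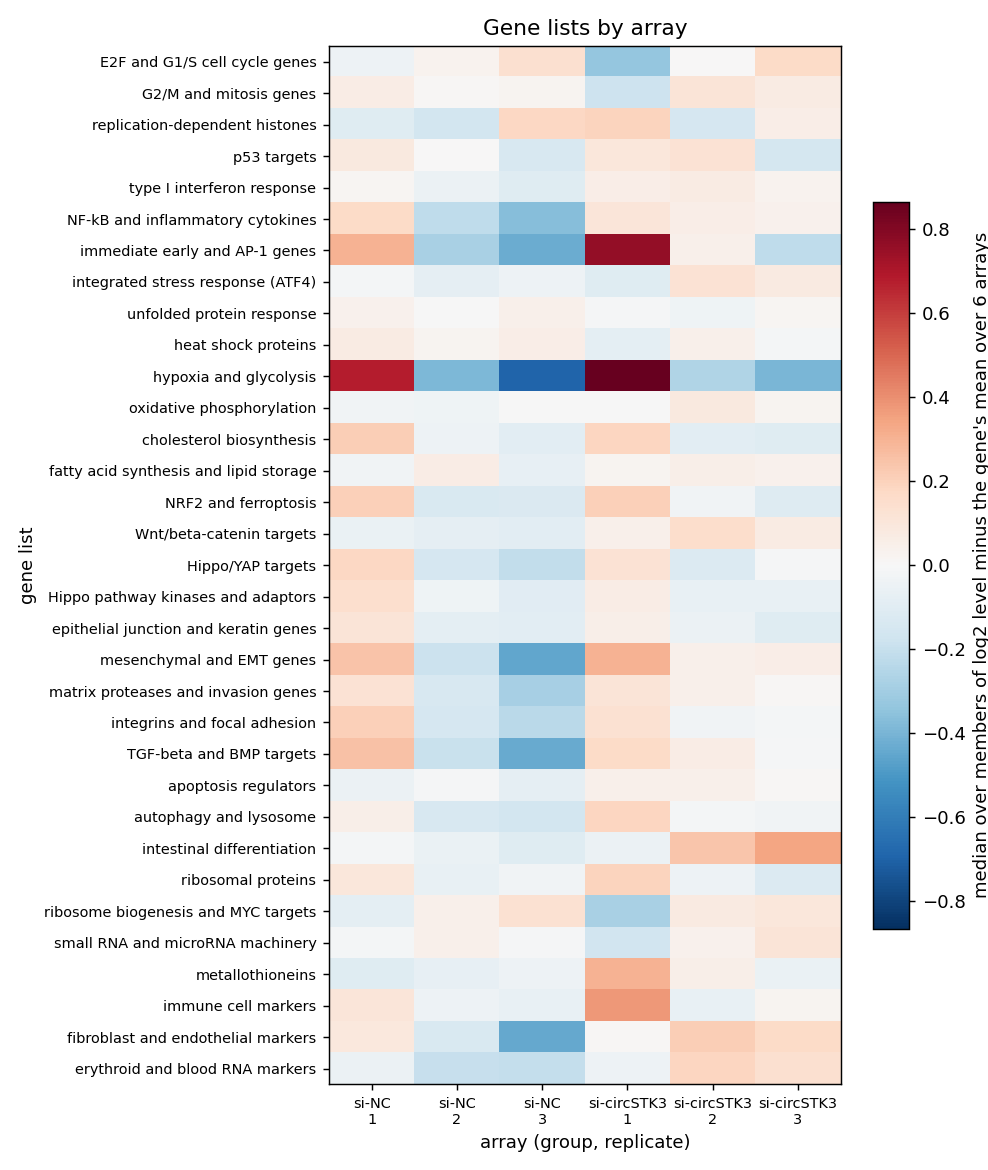
Median over the members of each of the 33 gene lists of the log2 level minus the gene's mean over the 6 arrays, with arrays in columns, lists in rows and the colour giving the value from blue (below) to red (above). The hypoxia and glycolysis list has the deepest colours, at 0.68 on si-NC replicate 1 and 0.86 on si-circSTK3 replicate 1 against -0.69 to -0.26 on the other 4 arrays.

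Hypoxia and glycolysis genes lay higher on replicate 1 of both groups than on the other 4 arrays. On slide 1, si-circSTK3 replicate 1 alone could be set against the 3 si-NC arrays, and the differences below rest on that 1 array. With the slide as a block 13 lists passed at the preset correlation, 9 higher and 4 lower, and 13 on slide 1 alone. With an estimated correlation 0 passed, with adjusted p from 0.772 to 0.879 for these 13. The median difference of the hypoxia list was 0.98, with ANKRD37 at 3.65 (SE 1.58), ALDOC at 2.09 (SE 0.96) and NDRG1 at 1.94 (SE 0.78), and si-NC replicate 1 was higher in this list than si-NC replicates 2 and 3 by a median of 1.18. Immediate early genes had a median of 0.84, with the transcription factors EGR1 at 1.80 (SE 0.84) and JUN at 1.70 (SE 0.70). The E2F and G1/S list lay at -0.36, with the replicative helicase subunit MCM5 at -0.99 (SE 0.27), the G2/M list at -0.19, with the cyclin CCNA2 at -0.78 (SE 0.16), ribosome biogenesis and MYC targets at -0.26 and heat shock proteins at -0.11. These example genes were chosen after their values were seen. Mesenchymal genes (0.34), NF-kB targets (0.33), NRF2 genes (0.35), metallothioneins (0.26), histones (0.25), ribosomal proteins (0.23) and immune cell markers (0.32) lay above 0. As a median deviation from the mean of the 6 arrays, si-NC replicate 1 was at 0.25 for mesenchymal genes, 0.16 for NF-kB targets and 0.21 for NRF2 genes, beside 0.30, 0.10 and 0.21 on si-circSTK3 replicate 1, so that in these lists the difference came from si-NC replicates 2 and 3. Under quantile normalization, normexp with 75th percentile scaling and normexp with quantile normalization the median kept its sign in all 13 lists. Its size stayed within 1.5 times in 7, among them E2F (-0.41, -0.32 and -0.39), hypoxia (0.88, 0.84 and 0.78) and metallothioneins (0.26, 0.25 and 0.22), and moved more in 6. Immune markers fell from 0.32 to 0.11, 0.03 and 0.09, mesenchymal genes from 0.34 to 0.27, 0.13 and 0.14, NF-kB targets from 0.33 to 0.26, 0.16 and 0.14, and NRF2 genes from 0.35 to 0.25, 0.19 and 0.17. Ribosomal proteins went from 0.23 to 0.05, 0.26 and 0.03, and heat shock proteins from -0.11 to -0.25, -0.09 and -0.19.

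**Figure D3:**
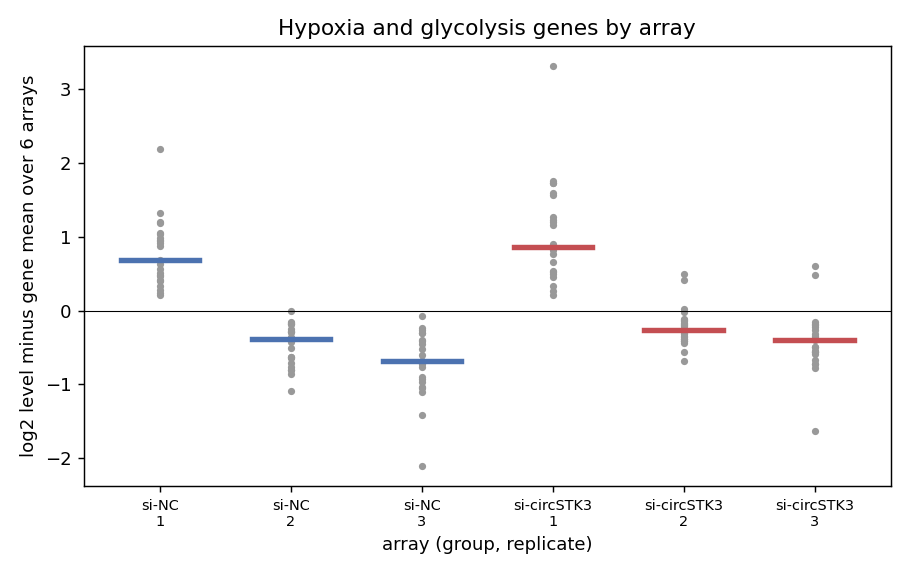
Log2 level minus the gene's mean over the 6 arrays for the 23 measured hypoxia and glycolysis genes, 1 grey point per gene and array, with a bar at the median, blue for si-NC and red for si-circSTK3. The medians are 0.68, -0.39 and -0.69 on si-NC replicates 1, 2 and 3 and 0.86, -0.26 and -0.39 on si-circSTK3 replicates 1, 2 and 3.

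Dim genes differed most between the slides. In the 5382 dimmest features, si-circSTK3 replicates 2 and 3 lay above si-NC by a median of 0.64 and replicate 1 by 0.09. The adenoviral E1A control probes, which stand for no human gene, lay higher by a median of 1.55 on slide 2 than on the si-NC arrays and by 0.15 on si-circSTK3 replicate 1. Whether RNA matching these probes was added was not checked here. Within si-circSTK3, the arrays of slide 2 differed from replicate 1 in 2976 features, 2265 higher and 711 lower, and with quantile normalization in 4112, 1892 higher and 2220 lower. Replicate 1 is a single array in this test, and its spread was taken from the other arrays. Slide 2 held no si-NC array, so for replicates 2 and 3 the slide and the silencing cannot be told apart.

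**Figure D4:**
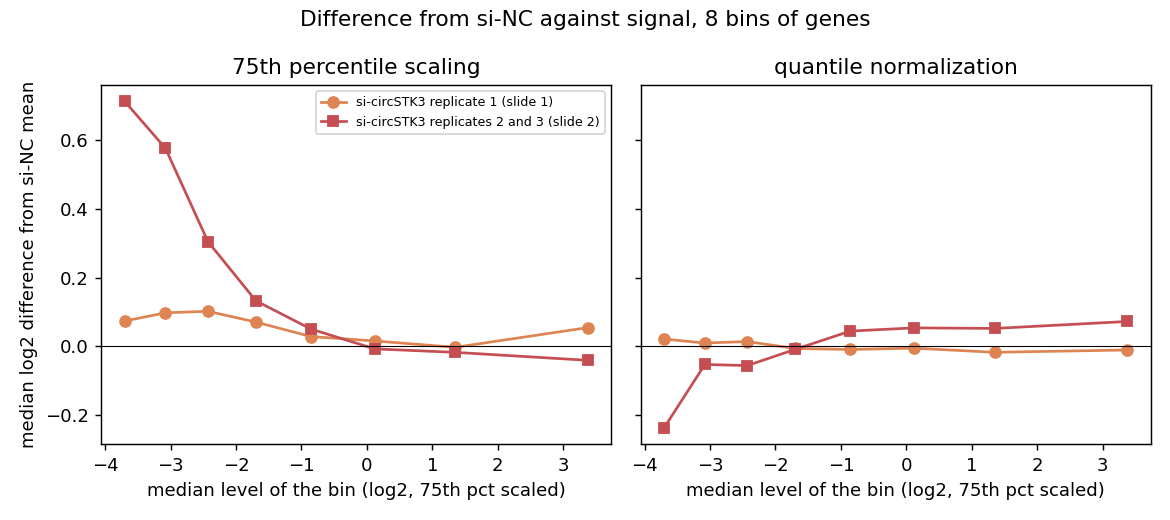
Median log2 difference from the si-NC mean, on the vertical axis, in 8 bins of features ordered by their mean level, on the horizontal axis, for si-circSTK3 replicate 1 (circles) and the mean of replicates 2 and 3 (squares), with 75th percentile scaling on the left and quantile normalization on the right. On the left the squares run from 0.71 in the dimmest bin to -0.04 in the brightest, and on the right from -0.24 to 0.07.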

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

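The test on control probes and the count over other splits of the arrays were chosen after the results were seen, as was quantile normalization without si-circSTK3 replicate 1. The bounds for the scaling and the silencing were written beforehand, but the explanation held to the silencing bound was narrowed, and its reading settled, after the value was seen, and that test decides nothing.

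A signal appeared in probes outside the gene comparisons. The 10 adenoviral E1A control probes of the array, with 32 spots each, were higher on si-circSTK3 replicates 2 and 3 than on si-NC by a median of 1.55 on the log2 scale, 10 of 10 higher with a range of 1.01 to 2.46. On si-circSTK3 replicate 1 the median was 0.15, and si-NC replicate 1 exceeded si-NC replicates 2 and 3 by 0.50.

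Replicates 2 and 3 of si-circSTK3 stood apart from the other 4 arrays, and set against si-NC without replicate 1 they gave 5294 features past the threshold. With quantile normalization 5661 features passed, 3216 of them shared with the 5294 in the same direction. For these 3216 the values argue against scaling between arrays as the whole cause. The balance did move with the scaling, from 4100 higher and 1194 lower to 2427 higher and 3234 lower. In the dimmest of the 8 bins the median difference of replicates 2 and 3 from si-NC moved from 0.71 to -0.24. In si-circSTK3 replicate 1 the 5294 features were shifted in the direction called by 0.115 of the shift in replicates 2 and 3. This restates the pattern, since these features passed only without replicate 1 and carry the shift of slide 2 as well. Both shifts were also taken from the same si-NC arrays. Whether silencing was alike in the 3 samples was therefore not decided. Nonspecific signal on slide 2 is a candidate explanation for dim genes that lay higher there, 3770 of the 5294. The E1A probes shifted by 1.55, which speaks to it only if no matching RNA was added, and that was not checked. Other control probes did not share this rise. The median negative-control signal on slide 2, 2.48 and 2.39, lay within the si-NC range of 1.32 to 4.41. The 3 brightest external control probes differed by -1.68, -0.90 and -2.14 between si-circSTK3 and si-NC replicates 2 and 3. Nonspecific signal also leaves the 1194 lower features open. A silencing that worked less well in sample 1, an exchanged label and the slide itself stay open, because circSTK3 was not measured and slide 2 held no si-NC array.

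Other splits of the 6 arrays into 3 and 3 could not settle whether chance gives the 0 features past the threshold in limma: a count of 0 is reached by every split, all 10 here, and 10 splits allow no share under 0.05. The highest of the others was 0. At an unadjusted p under 0.05 the real split gave 3538 features and the highest other gave 4828, with a smallest adjusted p of 0.0849. That split sets si-NC replicate 1 beside si-circSTK3 replicates 2 and 3, which is the real split with the 2 arrays numbered 1 exchanged. With the slide as a block the real comparison gave 2467 at that level.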

How the results depend on the processing

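Slide 1 alone, brighter genes only and quantile normalization without si-circSTK3 replicate 1 were chosen after the data were seen. The count of 0 features past the threshold in limma held under the alternatives set beforehand except the slide as a block, with 2 (1 higher, 1 lower, 2 at least 2-fold), and arrays left out, with 0 to 5294 (0 to 4100 higher, 0 to 1194 lower, 0 to 2116 at least 2-fold); without si-circSTK3 replicate 1 and with quantile normalization it was 5661 (2427 higher, 3234 lower, 1605 at least 2-fold). Of the lists, 0 passed in the main setting and 1 with normexp and 75th percentile scaling, 5 with no filter, 13 with the slide as a block, 13 on slide 1 alone, 1 with brighter genes only and the replicate block, and 0 to 4 with an array left out. With camera and an estimated correlation 0 lists passed in each of these settings. With fry 2 lists passed without si-circSTK3 replicate 1, under 75th percentile scaling and under quantile normalization, and 0 in the other settings named here. Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered arrays correlated at only 0.0718, 0.151 and 0.102 across genes, although every array correlated best with its own number. With the replicate block 0 features and 5 lists passed (0 with an estimated correlation), and 2717 features had an unadjusted p under 0.05. STK3 turned from -0.07 to 0.11 with the slide as a block and on slide 1 alone, and with an array left out it ranged from -0.186 to 0.0702, above 0 without si-NC replicate 1 (0.0702) and without si-circSTK3 replicate 2 (0.00328). Over 41 named genes and 20 alternatives, 698 of 756 values kept sign and side, 48 passed and 10 turned: CEACAM3 (-0.0738), SLC2A3 (-0.17) and CD68 (-0.0229) with normexp and 75th percentile scaling, SLC2A3 (-0.0240) with normexp and quantile, NUPR1 (-0.14) and HSP90B1 (0.17) with the slide as a block and on slide 1 alone, and SLC2A3 (-0.30) and CD68 (-0.14) without si-circSTK3 replicate 1 and with quantile normalization. The cause was not tested. The values that kept sign and side are not separate checks. For the named genes still measured, the filters, the trended and robust variances and the replicate block left the difference unchanged. The slide as a block and slide 1 alone gave the same difference. A value could also keep its sign and shrink, as CES1P1 did from 2.01 to 0.04 with normexp and 75th percentile scaling. Dim genes moved most between scalings, and whether signal over background limits them was not tested.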

Other observations

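The tests on the slide for the hypoxia list and on the external control probes were chosen after the results were seen, and the genes named next were singled out after their values were seen.

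Among brighter genes, HNRNPDL, an RNA-binding protein, was at 2.78 ± 0.01 (SD, n = 3) in si-NC and 2.34 ± 0.04 (SD, n = 3) in si-circSTK3, and IFT172, a ciliary transport protein, at 1.77 ± 0.07 and 2.33 ± 0.07. The differences were -0.44 (SE 0.11) and 0.57 (SE 0.12), each with a limma adjusted p of 0.281, and neither passed. On slide 1 they were -0.48 and 0.61. Of 7039 brighter features, 534 had an unadjusted p under 0.05, 271 higher and 263 lower, and 0 passed in limma. CCNE2, a cyclin of the G1/S transition, was at 7.74 on si-NC replicate 3 and between 0.76 and 1.44 on the other 5 arrays.

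Within si-circSTK3, some proliferation genes were higher on the 2 arrays of slide 2 than on replicate 1, which was a single array. With quantile normalization, 7 of 25 E2F and G1/S genes, 7 of 25 G2/M genes and 7 of 22 ribosome biogenesis and MYC targets passed, all higher, against 1892 of all 21529 features. With 75th percentile scaling 2, 5 and 2 did, against 2265 of 21529, so that the share in the E2F and ribosome biogenesis lists was below that over all features. The cyclin CCNB1 was higher by 0.87 (SE 0.14, limma adjusted p = 0.0207), AURKA by 0.71 (SE 0.15) and the pyrimidine synthesis enzyme CAD by 1.24 (SE 0.27). The list medians were 0.42, 0.29 and 0.39, and with quantile normalization 0.51, 0.41 and 0.52. At the preset correlation the adjusted p was 0.0403 for the E2F list, 0.0728 for the G2/M list and 0.0417 for ribosome biogenesis. With an estimated correlation the adjusted p was 0.865 for each, and 0.832 with quantile normalization. Of the 10 lists that passed at the preset correlation, 2 were higher and 8 lower, and with an estimated correlation 0 passed, with adjusted p of 0.865 for each. The 8 were hypoxia (-1.32), immediate early genes (-0.86), cholesterol biosynthesis (-0.29), histones (-0.28), NRF2 genes (-0.26), ribosomal proteins (-0.20), epithelial genes (-0.14) and immune markers (-0.12), with 5 of 15 immune markers lower, among them CD3E at -1.34 (SE 0.16) and CD163 at -1.38 (SE 0.22). With quantile normalization the E2F, G2/M and ribosome biogenesis lists had smaller adjusted p at the preset correlation than with 75th percentile scaling. Some lists passed with fry under quantile normalization, and none did under 75th percentile scaling. These tests rest on the single array of replicate 1. The group comparison covers both slides, and these differences lie between slides of 1 group.

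Hypoxia and glycolysis genes were high in replicate 1 of both groups: 23 of 23 on si-NC replicate 1 against si-NC replicates 2 and 3, and 21 of 23 on si-circSTK3 replicate 1 against its replicates 2 and 3, by medians of 1.18 and 1.32. ANKRD37 differed by 3.79 among the si-NC arrays, ALDOC by 2.34 and PDK1 by 2.21. The slide as the cause is argued against in si-NC by the 1.18 among its arrays, which shared a slide. In si-circSTK3, replicate 1 lay on another slide than replicates 2 and 3, so slide and replicate cannot be told apart there. A state shared by the samples numbered 1, whatever its nature, stays open. Over 7021 brighter genes outside the list the deviations of the replicate 1 arrays correlated across genes between groups at r = 0.116 (bootstrap interval 0.0628 to 0.172, Spearman 0.28). This r lay between the bounds set in advance, and genes are not independent replicates. No biological explanation from the design was tested, since the groups cross this pattern.

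The si-circSTK3 minus si-NC differences of the arrays numbered 1 ran against those of the arrays numbered 2 and 3, with r = -0.298 across the same 7021 genes (bootstrap interval -0.326 to -0.268), though Spearman's value was -0.07, so that fewer, strongly differing genes carry it. A label exchanged between the arrays numbered 1 is a candidate explanation. With them exchanged, 4828 features had an unadjusted limma p under 0.05 and the smallest adjusted p was 0.0849, against 3538 and 0.260. The share of probes well above background was 96.1% on si-NC replicate 1 and 73.7% on si-circSTK3 replicate 1. Each lay nearer the other group's numbers 2 and 3 (94.6% and 95.3%, 79.1% and 73.9%). Neither value can tell an exchange from a difference in array signal. Replicates 2 and 3 of si-circSTK3 were alone on slide 2, and si-NC replicate 1 exceeded si-NC replicates 2 and 3 by 0.50 in the E1A probes. The arrays numbered 1 correlated best with each other (0.990), which an exchange would leave unchanged. Over all genes, however, si-NC replicate 1 correlated better with si-NC replicates 2 and 3 (0.983 and 0.981), on its slide, than with si-circSTK3 replicates 2 and 3 (0.974 and 0.971), and si-circSTK3 replicate 1, on that slide too, correlated better with si-NC replicates 2 and 3 (0.979 and 0.979) than with its own group (0.968 and 0.965). The slide would give both, an exchange without the slide only the second. Hybridization or labelling is a candidate explanation too, since 3 of the 3 brightest of 25 external control probes differed in the same way, and no test here decides between them, since circSTK3 was not measured. The brightest, ERCC-00062_278, lay at 1.60, 3.13 and 2.79 on si-NC replicates 1, 2 and 3 and at 2.50, 1.28 and 1.29 on si-circSTK3 replicates 1, 2 and 3, a difference of 0.90 for number 1 and -1.68 for numbers 2 and 3. Whether such control RNA was added is not given in the sources used here.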
